A study of Oryza sativa with 6 samples.

How the data were processed

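The series holds 6 libraries of mesocotyl RNA from rice cultivar P25, each made from 1 RNA pool. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was captured with oligo(dT) beads, and cDNA libraries were sequenced in paired ends on an Illumina HiSeq instrument. Groups follow the labels: darkness for 1, 3 or 5 days, and 5 days of darkness followed by 30 min, 60 min or 24 h of light. The kit named marks no strand, so reads from a locus and an overlapping antisense partner cannot be told apart.

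The authors deposited 1 table of FPKM values per locus and library, per the file headers. The aligner and counter behind these columns are not given in the sources used here. The submitters' processing notes name Bowtie 0.12.2 and the build mm8, a mouse build, without saying what either was used for; a mouse build cannot have given rice loci. Of 35500 loci, 27377 carry identifiers of the form that a transcript assembler gives (MSTRG), and 33444 carry gene names that begin with ZS. A set of 730 loci merges several gene names. The table also gives the authors' p-value and q-value per locus, per the file headers; these were copied and not used further. No position is given per locus, so no coordinates are printed. None of the gene names matched the table of reference genes for assembly ASM3414082v1 (0 matches), so product names are those the deposited table gives. Product names come from similarity, and several loci can share one, so values of close paralogs such as the pair of actin-1 loci are uncertain where reads could fit both.

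FPKM values hold no whole read counts, so no count test was run. Relative depth was read from loci with 1 transcript and under 0.1 FPKM in both libraries of a pair, where the ratio of values takes a preferred step. Against the 1-day dark library, the most common ratio was 1.216 for the 5-day dark library, 1.162 for 30 min, 1.188 for 60 min and 1.245 for 24 h of light, which corresponds to depths of 0.82, 0.86, 0.84 and 0.80 times that library. For the 3-day dark library there were 2 steps, at 2.017 and 1.008, which correspond to 0.50 and 0.99, and the pairs did not settle which holds. Other pairs also had a second step, such as 0.608 (depth 1.64) for the 5-day dark library. For 24 h against 30 min of light the most common step was 0.536 (depth 1.87), so the other depths are not settled either. Only 2.2% to 4.3% of loci lay within 0.3% of the step for any pair, so total depth is unknown and no interval from counting error is given.

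Differences were computed as log2((FPKM + 1)/(FPKM + 1)), which understates differences of low loci, for loci with at least 1 FPKM in at least 1 library (23787 loci). A locus was counted as higher or lower at a difference of 1 or more on this scale, that is 2-fold. There are no replicates, so this is a rule of size and not a test. The comparisons were 3 against 1 day and 5 against 3 days of darkness, each light library against the 5-day dark library, and consecutive light libraries against each other. The 3 light comparisons share the 5-day dark library, so the overlap of their loci was not used, and each was repeated with the 3-day dark library as control. An exact 0 can be a failed estimate, so values are given as listed and no fold is given against a 0.

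For gene lists, the median difference was set against 10000 random lists of the same size drawn from 20 bins of mean expression. A median was described as outside the random range at or beyond the 2.5 or 97.5 percentile, as a description of these libraries only. Of 43 lists fixed before the data were examined, 40 had at least 3 measured members. Strigolactone and karrikin loci, secondary wall cellulose synthases and alpha-amylases had 2 each and are given as values. Single genes fixed by identifiers of another rice annotation were matched through the deposited product name after the table had been opened, since the identifiers differ. Peroxidases of other families that the peroxidase pattern caught were left out once the table had been opened. Lists of plastid ribosomal proteins and of cuticle and epidermis loci were added after the table had been opened, before their values were computed. Pathways as the authors' deposited table assigns them were examined afterwards, with 2000 random lists each. Of these, the carbon fixation and the porphyrin and chlorophyll pathways were also split, after their values were seen, by whether the product name contains chloroplast. On simulated data made from the 5-day dark library over 23787 loci, 100 lists of 20 loci with a true shift of 0, 0.5, 1 and 2 gave 5, 57, 100 and 100 lists at or above the 97.5 percentile. Simulated loci were drawn at random and varied independently, with a standard deviation of 0.8 on the log2 scale. Loci of a gene family may move together, which neither this simulation nor the random lists allow for.

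Genes named in the text follow a rule fixed before the data were examined: the 8 highest and 8 lowest loci per main comparison with a product name and at least 10 FPKM in the higher library, for light also outside the range of the 3 dark libraries, from which those given are a selection; up to 4 members per described list with the largest differences; and all measured single genes fixed for light signalling, gibberellin, brassinosteroid, jasmonate, strigolactone and reference loci. A locus chosen in one comparison is also quoted in others. Named outside this rule were loci listed at an exact 0, the locus with the highest share of the 3-day dark library and loci given under other observations. Members of further lists, such as the clock, antenna and JAZ lists, could also be named in full. Alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, scaling to the median ratio of loci, to one fixed sum per library (TPM, which also lowers the weight of the pseudocount) or to the mean of the library sums, the 3-day dark library as control, and the range of all 3 dark libraries. All values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.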

Results

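Poly(A) RNA was sequenced from the mesocotyl of the indica rice cultivar P25. The mesocotyl is the stem-like segment between seed and coleoptile that lengthens in darkness and carries the shoot to the soil surface. There were 6 RNA pools, each sequenced as 1 library, so every group held 1 library. Dark-grown seedlings were sampled 1, 3 and 5 days after sowing, and 5-day dark-grown seedlings after 30 min, 60 min or 24 h of light. The series title places the question in the light inhibition of mesocotyl elongation. None of the differences below has a replicate check, so no p-value is given, and "higher" and "lower" describe these libraries only. Values are FPKM, fragment counts scaled to transcript length and library size, as deposited. Of 35500 loci, 23787 reached at least 1 FPKM in some library. Library sums lay between 336212 and 359808 FPKM. The number of loci at 1 FPKM or more was 15983, 16645 and 18612 in the dark libraries at 1, 3 and 5 days, and 17986, 18569 and 17897 after 30 min, 60 min and 24 h of light. In the 3-day dark library 1 locus without a product name, ZS07g0251700, held 14.9% of all FPKM.

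Among common reference loci, those for ubiquitin-conjugating enzyme lay closest together. ZS05g0471300 ranged from 97 to 126 FPKM over the 6 libraries, and ZS01g0694900 from 13.5 to 18.3. The actin-1 locus ZS03g0650200 stood at 435 FPKM at 1 day and 90.1 at 5 days in the dark, and the second actin-1 locus, ZS05g0445900, at 25.6 and 52.5. Elongation factor 1-alpha (ZS03g0074700) lay between 249 and 416 FPKM. The initiation factors eIF4A-1 (ZS06g0636000) and eIF4A-3 (ZS02g0054500) lay between 144 and 337 and between 83.0 and 137 FPKM. An exact 0 was not always absence. SNW/SKI-interacting protein (ZS02g0642300), a splicing factor used by every cell, was listed at 0 at 1 day and at 32.6 to 89.0 FPKM elsewhere. Between 4 and 10 loci per library were listed at 0 there and at 10 FPKM or more in the other 5 libraries.

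From 1 to 3 days of darkness, loci of growth and division were lower. Of 97 cytosolic ribosomal protein loci, 79 were at least 2-fold lower and 1 was higher (median log2 difference -1.31). Of 38 cell cycle loci, 25 were lower and 1 higher (-1.58), among them cyclin-dependent kinase B2-1 (ZS08g0604500), which acts at mitosis, at 32.8 and 6.93 FPKM. Cyclin-B1-5 (ZS05g0510900) stood at 25.5 and 5.62. Core histones had 11 of 21 loci lower and none higher (-1.04), for example H2A.7 (ZS12g0260000) at 38.0 and 7.28 FPKM. One histone H4 locus (ZS09g0414200) was listed at 116 and 0, but at 134 to 309 FPKM in the later libraries, so that 0 can be a failed estimate. Each of these 3 medians lay at the 0.0 percentile of 10000 random lists of matched expression. For the ribosomal proteins, the random range itself ran from -0.66 to -0.17, so other loci of that expression were also lower. The count of 79 loci does not take this out. For cell cycle loci and core histones the random range ran from -0.42 to 0.19 and from -0.71 to 0.21. Cuticle and epidermis loci, markers of a tissue, were lower at 9 of 21 and higher at 3 (-0.80, percentile 0.1), while the deposited pathway Cutin, suberine and wax biosynthesis (72 loci) lay inside the random range (0.08).

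Xyloglucan endotransglucosylases and primary wall cellulose synthases were also lower, while other wall loci were mixed or higher. Xyloglucan endotransglucosylases, which cut and rejoin wall xyloglucan, were lower at 9 of 15 loci and higher at 2 (-1.55, percentile 0.0). ZS06g0631400 stood at 336 FPKM at 1 day and 18.9 at 3 days, and ZS07g0384000 at 67.3 and 2.11. The primary wall cellulose synthases CESA1 (ZS05g0090500), CESA5 (ZS03g0799300) and CESA6 (ZS07g0191200) stood at 274, 54.4 and 169 FPKM at 1 day and at 93.8, 30.8 and 28.4 at 3 days (median -1.54, percentile 1.9). The secondary wall subunits CESA4 (ZS01g0613900) and CESA9 (ZS09g0283800) were higher at 3 days, at 9.71 and 4.22 against 27.9 and 13.4 FPKM. Expansins, which loosen walls, were mixed, with 7 of 26 higher and 9 lower and a median inside the random range (-0.09), as were phenylpropanoid and lignin loci, with 9 of 44 higher and 8 lower (0.03). Expansin-A1 (ZS04g0221900) stood at 116 and 2.58 FPKM, expansin-A2 (ZS01g0680000) at 124 and 5.20, but expansin-B7 (ZS03g0011900) at 7.82 and 196. Tubulins had a median of -0.95 (percentile 3.8), and 3 of 5 seed storage loci were lower and 1 higher (-1.16, percentile 0.8). The starch-degrading alpha-amylases ZS04g0489400 and ZS06g0647300 stood at 15.4 and 0.138 FPKM at 1 day and at 20.2 and 5.12 at 3 days.

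Higher at 3 days were clock loci, with 4 of 7 at least 2-fold higher and 2 lower (median 1.21, percentile 99.8). GIGANTEA (ZS01g0082000) stood at 10.1 and 43.1 FPKM and the blue-light clock protein adagio-like 3 (ZS11g0484900) at 1.99 and 12.7; the labels used here give no hour of sampling. The deposited pathway Circadian rhythm - plant (134 loci) lay inside the random range (0.01, percentile 92.9), with 24 loci higher and 19 lower. The highest differences among loci with a product name included metallothionein 3B (ZS05g0121200), a metal-binding protein, at 1.03 and 435 FPKM and metallothionein 4C (ZS12g0448700) at 19.3 and 2566. The transcription factor MYB59 (ZS01g0815200) stood at 1.04 and 111 FPKM, a universal stress protein (ZS05g0355900) at 0.400 and 88.3, and the pathogenesis-related protein PRB1-2 (ZS10g0126800) at 1.75 and 149. On the lower side, a Bowman-Birk trypsin inhibitor (ZS01g0031600 and ZS01g0031700 merged) was listed at 6222 and 0 FPKM. The subtilisin-chymotrypsin inhibitor cluster headed by ZS12g0413600 stood at 3204 and 18.4, and cortical cell-delineating protein (ZS10g0444600) at 350 and 1.35. Lipid-transfer protein 1 (ZS01g0679800) was listed at 332 and 0, proline-rich protein 4 (ZS10g0059800) at 135 and 0, and an ERECTA-like kinase (ZS02g0664900) at 74.6 and 0. Over all loci, 3218 were at least 2-fold higher and 3443 lower. The balance turned with scaling, to 3959 and 2863 with the median ratio of loci and to 3463 and 3084 with every library set to the mean of the 6 library sums.

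**Figure D1:**
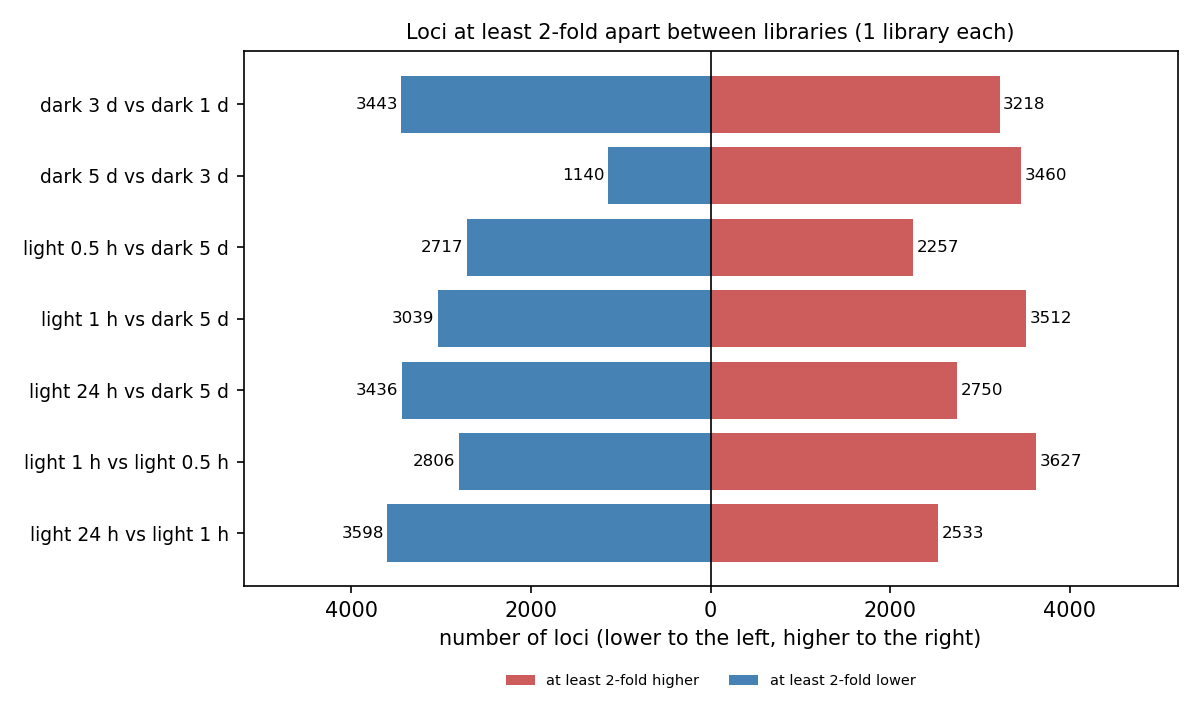
Number of loci at least 2-fold higher (red, to the right of 0) or lower (blue, to the left) in each comparison of 2 libraries, on the log2(FPKM + 1) scale among 23787 loci. The 5-day against 3-day dark comparison is the most one-sided, with 3460 higher and 1140 lower. Scaled to the median ratio of loci, it held 2520 higher and 1677 lower.

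From 3 to 5 days of darkness, photosynthesis loci were higher although both libraries came from seedlings kept without light. The chlorophyll-binding antenna list had 5 of 7 loci at least 2-fold higher and none lower (median 2.5). Photosystem and carbon fixation loci had 10 of 16 higher and none lower (1.88), and chlorophyll biosynthesis 7 of 8 higher and none lower (2.04). All 3 medians lay at the 100 percentile. The wider deposited pathways Carbon fixation in photosynthetic organisms (131 loci, 0.33) and Porphyrin and chlorophyll metabolism (123 loci, 0.33) lay inside the random range. Their 21 and 23 loci with a chloroplast product name had medians of 1.53 and 1.06 (percentile 100 each), and the other 110 and 100 loci medians of 0.26 and 0.10. The small subunit of Rubisco (ZS12g0195100), the carbon-fixing enzyme, stood at 0.142 and 125 FPKM. Oxygen-evolving enhancer 2 (ZS07g0050800) stood at 0.0379 and 43.8, chloroplast ferredoxin-1 (ZS08g0011300) at 0.188 and 87.8, and chloroplast fructose-bisphosphate aldolase (ZS11g0066900) at 0.0374 and 207. Antenna protein CP29.1 (ZS07g0459100) was listed at 0 and 13.0. Protochlorophyllide reductase B (ZS10g0390600), which makes chlorophyllide, stood at 0.308 and 15.8 FPKM. In the light-signalling list 3 of 12 loci were higher and none lower (0.90, percentile 99.5), and B-box factors had 5 of 16 higher and none lower (0.66, percentile 98.6). Shoot meristem and root marker medians lay inside the random range (0.18 and -0.27).

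Core histones were higher at 2 of 21 loci (0.60, percentile 99.7), while the cell cycle list lay inside the random range with all 38 loci within 2-fold (0.25). Of the 2 histone loci, the H4 locus ZS09g0414200 was listed at 0 at 3 days and at 143 FPKM at 5 days. That 0 can be a failed estimate. Class III peroxidases, secreted enzymes that act on wall phenolics and peroxide, had a median of -0.27 (percentile 0.0), with 5 of 45 loci lower and 3 higher. Peroxidase P7 (ZS06g0457400) stood at 50.1 and 4.48 FPKM and peroxidase 11 (ZS06g0190100) at 73.6 and 22.3. Aquaporins, the water channels, had a median of -0.43 (percentile 0.0), with TIP2-1 (ZS02g0542000) at 41.9 and 12.7 FPKM and PIP2-7 (ZS09g0398300) at 0.0570 and 64.9. Tubulins lay at -0.24 (percentile 1.0), and glutathione S-transferases at -0.02 (percentile 0.8). Among single loci, dirigent protein 1 (ZS11g0580200) stood at 1.86 and 764 FPKM, whereas dirigent protein 4 (ZS10g0236100) was listed at 88.0 and 0. Gibberellin 20-oxidase 1 (ZS03g0824300), a late step of gibberellin synthesis, stood at 6.17 and 21.1. CBL-interacting protein kinase 2 (ZS07g0577200) stood at 84.3 and 1.93, and the factor HEC2 (ZS09g0323000) was listed at 29.1 and 0. Over all loci, 3460 were higher and 1140 lower, and the median over loci lay at 0.27, to which the list medians here are to be compared. The locus ZS07g0251700 held 14.9% of all FPKM in the 3-day library. A share that large lowers the FPKM of all other loci there, and scaling to library sums keeps that locus in the sum. How much of the 0.27 comes from this was not tested. Scaled to the median ratio of loci, the median over loci was 0.02. The split was then 2520 higher and 1677 lower, that is 60.0% higher in place of 75.2%. The phenylpropanoid and lignin median was -0.04 in place of 0.09 (percentile 1.6 as deposited).

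After 30 min of light, jasmonate and defence regulators were higher than in the 5-day dark library. Of 11 JAZ loci, which encode repressors induced by the wound hormone jasmonate, 8 were at least 2-fold higher (median 1.82, percentile 100). TIFY 11c (ZS03g0077200) stood at 11.2 FPKM in the dark and 139 after 30 min, TIFY 11a (ZS03g0077100) at 3.71 and 50.6, and TIFY 9 (ZS04g0484700) at 0.322 and 21.3. The 1 lower member, TIFY 11b (ZS03g0077250), was listed at 0 after 30 min and at 14.2 to 65.7 in every other library. That 0 can be a failed estimate, and values of close paralogs are uncertain. Of the jasmonate synthesis loci, allene oxide synthase 1 (ZS03g0714600) was listed at 0 and 48.8 FPKM and 12-oxophytodienoate reductase 7 (ZS08g0538200) at 30.4 and 69.4. Allene oxide cyclase 3 (ZS11g0268400 and ZS11g0268300 merged) stood at 3.93 and 7.20, and allene oxide synthase 2 (ZS03g0115700) at 0.359 and 0.325 (list median 0.95, percentile 98.9). WRKY factors had 23 of 49 loci higher and 3 lower (0.95, percentile 100), with WRKY28 (ZS06g0572300) at 7.02 and 75.7 FPKM and WRKY 29 (ZS12g0024000) at 1.91 and 28.4. Ethylene response factors had 14 of 39 higher and 4 lower (0.39, percentile 99.9), lipoxygenases 2 of 6 higher and 1 lower (0.83, percentile 99.4), and glutathione S-transferases 7 of 23 higher and 1 lower (0.87, percentile 100). The glutathione S-transferase median lay inside the random range against the 3-day dark library (0.43, percentile 84.2).

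Light-signalling loci differed among themselves. HY5 (ZS01g0075000), a factor that promotes light-grown development and restrains stem elongation, stood at 2.26 and 8.57 FPKM, and COP1 (ZS02g0659100), the ligase that marks it for breakdown in darkness, at 7.87 and 10.3. PIF1 (ZS04g0748700), a repressor of light responses, stood at 9.96 and 5.63, and the PIF4 loci ZS07g0052200 and ZS12g0491200 at 5.11 and 1.71 and at 2.40 and 0.717. Phytochrome A (ZS03g0651500), the main light receptor of dark-grown seedlings, stood at 63.6 and 37.4, phytochrome B (ZS03g0205300) at 14.1 and 10.3, and phytochrome C (ZS03g0694400) at 4.0 and 2.03. Cryptochrome-1 (ZS02g0441500) stood at 8.70 and 4.37 and cryptochrome 2 (ZS02g0501600) at 9.17 and 11.8. The chloroplast regulators GLK1 (ZS06g0309500) and GLK2 (ZS01g0144900) were listed at 5.11 and 0 and at 2.72 and 0.0559. With 3 of 12 loci lower and 1 higher, the list median was -0.74 (percentile 0.2); against the 3-day dark library it was 0.08.

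Among gibberellin loci, a gibberellin 2-oxidase (ZS01g0620700), an enzyme that inactivates the growth hormone, stood at 0.690 and 14.6 FPKM, and gibberellin 20-oxidase 1 at 21.1 and 4.30. The 3-day dark level of gibberellin 20-oxidase 1, given above, was nearer to its 30-min than to its 5-day dark level. The other 7 measured members lay within 2-fold and the list median inside the random range (-0.05). The brassinosteroid loci, cytochrome P450 85A1 (ZS03g0517400), the receptor locus ZS01g0578700 and ILI1 (ZS04g0769300), stood at 6.93, 30.6 and 0.364 FPKM in the dark and at 10.8, 25.2 and 1.04 after 30 min. The karrikin receptor D14L (ZS11g0268600) stood at 82.4 and 21.9, and D27-like (ZS08g0020500), a strigolactone synthesis locus, was listed at 3.07 and 0. Phenylpropanoid and lignin loci had 10 of 44 higher and 4 lower (0.28, percentile 98.7), with a phenylalanine ammonia-lyase (ZS05g0436300), which opens the pathway, at 4.62 and 64.5 FPKM. The cytochrome P450 CYP73A100 (ZS02g0316000) stood at 0.922 and 50.9. Class III peroxidases were higher at 11 of 45 and lower at 1 (0.42, percentile 100), and expansins at 5 of 26 and 1 (0.50, percentile 99.9). Against the 3-day dark library the peroxidase median was low among matched lists (0.07, percentile 1.1), and those of lignin loci (0.26, percentile 39.1) and expansins (0.37, percentile 65.7) lay inside the random range. Cytosolic ribosomal proteins (0.67, 13 of 97 higher and 3 lower), cell cycle loci (0.59, 7 of 38 higher) and core histones (0.72, 5 of 21 higher) lay at the 100 percentile. LEA protein Lea5-D (ZS01g0233800) stood at 9.25 and 215 FPKM.

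Photosynthesis loci were lower after 30 min of light than in the 5-day dark library. Antenna loci were lower at 5 of 7 (median -2.34), photosystem and carbon fixation at 10 of 16 (-1.84) and chlorophyll biosynthesis at 5 of 8 (-1.65), with none higher. These medians lay at the 0.0 percentile. The pathways Carbon fixation in photosynthetic organisms (0.03, percentile 30.4) and Porphyrin and chlorophyll metabolism (percentile 51.4) lay inside the random range, with their chloroplast-named loci at -0.78 and -1.04. Against the 3-day dark library the medians were 0.04, 0.13 and 0.22, inside the random range. The Rubisco small subunit stood at 0.473 FPKM after 30 min and ferredoxin-1 at 0.374. Antioxidant enzymes (-0.41, percentile 0.6) were also low against the 5-day library, but inside the random range against the 3-day library (0.10, percentile 5.1). Heat shock proteins were low among matched lists against both, at -0.27 (percentile 0.6) and 0.12 (percentile 2.5). Shoot meristem and root marker medians lay inside the random range (-0.10 and 0.84). Dirigent protein 1 stood at 764 and 0.401 FPKM. Over all loci, 2257 were at least 2-fold higher and 2717 lower than in the 5-day dark library. Of these, 1088 and 182 lay at least 2-fold outside the range of all 3 dark libraries. With the 3-day dark library as control the balance turned, to 3058 higher and 1166 lower.

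**Figure D2:**
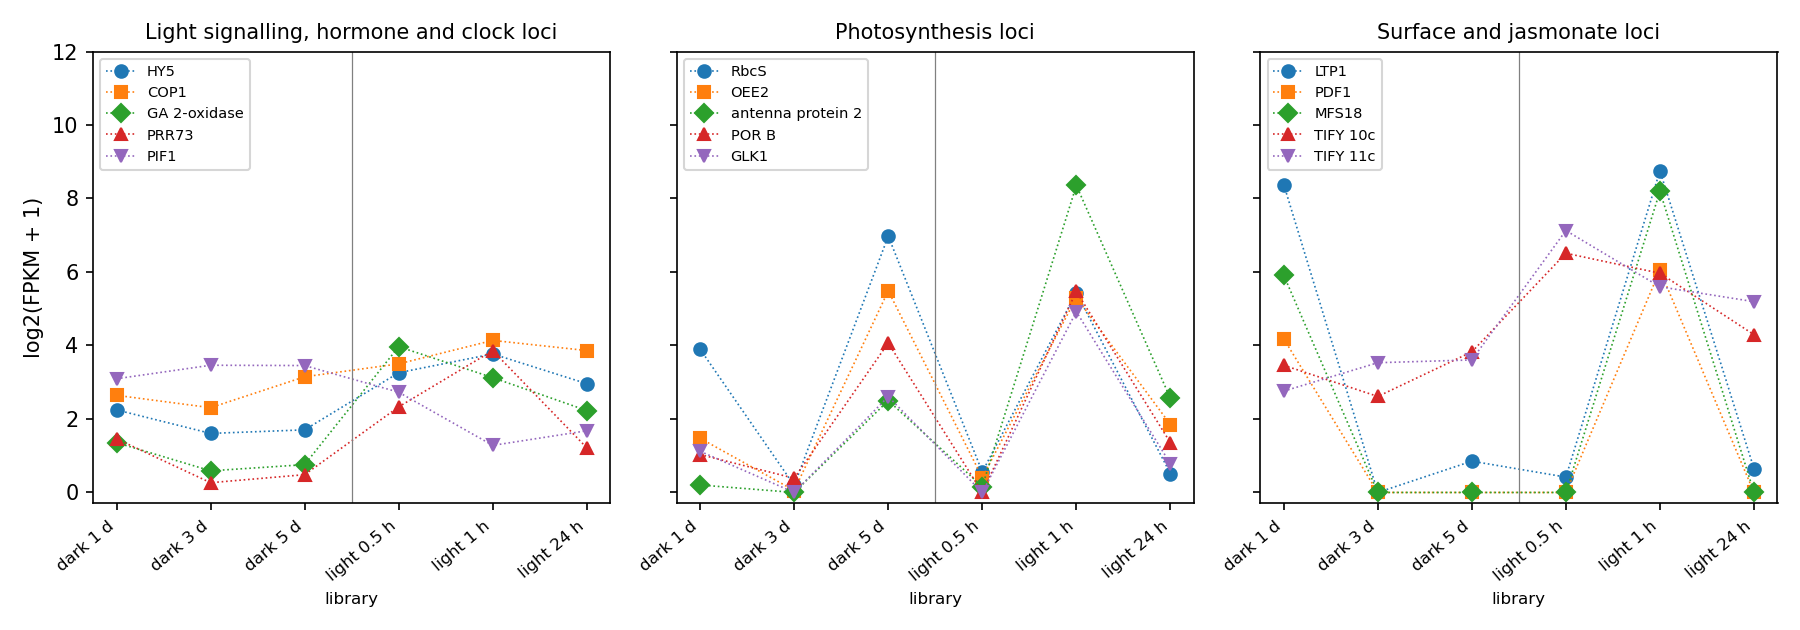
Expression of selected loci in the 6 libraries, as log2(FPKM + 1), with 1 point per library and dotted lines only to guide the eye; the grey line parts dark from light libraries. HY5, COP1 and PRR73 are highest after 60 min of light, RbcS, OEE2, POR B and GLK1 in the 5-day dark and 60-min libraries, antenna protein 2 after 60 min, LTP1, PDF1 and MFS18 in the 1-day dark and 60-min libraries, and the TIFY loci are highest after 30 min.

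After 60 min of light, antenna loci were higher than in the 5-day dark library at 7 of 7 (median 3.49, percentile 100). Chlorophyll a-b binding protein 2 (ZS01g0462400) stood at 4.66 FPKM in the dark and 327 after 60 min, ZS03g0506800 at 4.22 and 135, and protein 1B-21 (ZS06g0257900) at 9.07 and 112. Chlorophyll biosynthesis was higher at 4 of 8 loci and lower at none (1.02, percentile 98.9). Its ChlH subunit of magnesium chelatase (ZS03g0216600 and ZS03g0216700 merged) stood at 6.01 and 34.1, and chlorophyllide a oxygenase (ZS10g0458400) at 4.41 and 21.1. Photosystem and carbon fixation loci were mixed, with 6 of 16 higher and 2 lower (0.11, inside the random range). The pathway Carbon fixation in photosynthetic organisms was low (-0.20, percentile 0.2), with 9 of 131 loci higher and 27 lower. Its chloroplast-named loci lay at 0.04, inside the random range, and the other 110 at -0.23 (percentile 0.1). Plastocyanin (ZS06g0010500) was listed at 0 and 42.6, while sedoheptulose-1,7-bisphosphatase (ZS04g0233900) stood at 57.8 and 16.4 and the Rubisco small subunit at 125 and 42.3. The early light-inducible proteins HV60 (ZS07g0092400) and HV58 (ZS01g0151600), which protect plastids as they green, were listed at 0.0217 and 0 in the dark and at 9.46 and 11.4 after 60 min (list median 2.02, percentile 99.9, with 2 of 4 loci higher and the others within 2-fold).

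HY5 stood at 12.6 FPKM, COP1 at 16.6, GLK1 at 29.3 and GLK2 at 9.42, all above the 3 dark libraries, and PIF1 at 1.43 and phytochrome A at 23.2, both below them. Phytochromes B and C stood at 12.3 and 5.61, cryptochromes 1 and 2 at 4.26 and 10.8, and the PIF4 loci at 5.46 and 1.28. The clock regulator PRR73 (ZS03g0176700) stood at 0.399 in the dark and 13.5 after 60 min. The gibberellin 2-oxidase ZS01g0620700 stood at 7.73 and gibberellin 20-oxidase 1 at 2.31, and D14L at 37.2 and D27-like at 12.3. JAZ loci were higher at 6 of 11 and lower at none (1.08, percentile 100), while jasmonate synthesis loci lay inside the random range (0.71). Among auxin-responsive Aux/IAA loci, whose list median lay inside the random range (0.34), IAA14 (ZS03g0740400) stood at 1.85 and 26.8 FPKM and IAA10 (ZS02g0707200) at 23.5 and 82.4. Cytokinin response and breakdown had 4 of 12 lower and 2 higher (-0.61, percentile 1.1), with cytokinin dehydrogenase 11 (ZS08g0539300) at 15.1 and 3.69. The cytokinin median lay inside the random range against the 3-day dark library (-0.19).

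Division loci, tubulins and primary wall cellulose synthases were higher after 60 min. Cell cycle loci were higher at 25 of 38 and lower at 1 (1.51), core histones at 12 of 21 and 1 (1.11), tubulins at 7 of 10 and 1 (1.26) and ribosomal proteins at 39 of 97 and none (0.93), each at the 100 percentile. Cyclin-D6-1 (ZS07g0457600) stood at 2.12 and 21.7 FPKM, histone H2A (ZS05g0020200) at 28.2 and 253, and the 3 primary wall cellulose synthases CESA1, CESA5 and CESA6 at 202, 59.8 and 112 (median 1.54, percentile 99.7). Expansin-A7 (ZS03g0768400) stood at 7.33 and 53.6, with the expansin median inside the random range (0.28), as was that of xyloglucan endotransglucosylases (-0.01). The tubulin (0.68, percentile 86.5) and primary wall cellulose synthase (1.10, percentile 92.3) medians lay inside the random range against the 3-day dark library. Heat shock proteins were low against both dark libraries (-0.33, percentile 0.9, and -0.26, percentile 0.0). The cell cycle, histone, ribosomal protein and primary wall cellulose synthase lists were also lower at 3 than at 1 day of darkness, and cuticle and epidermis loci were higher after 60 min as well (1.03, percentile 100). The pathway Cutin, suberine and wax biosynthesis lay inside the random range (-0.02), with 12 of 72 loci higher and 11 lower.

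Among the single loci with the highest differences at 60 min, protodermal factor 1 (ZS01g0106400), made in the outermost cell layer, was listed at 65.3 FPKM, MFS18 protein (ZS01g0156200) at 293 and proline-rich protein 4 at 298. All 3 were listed at 0 in the 5-day dark library. Lipid-transfer protein 1 stood at 431 against 0.805, and a GDSL esterase (ZS05g0430300) at 88.6 against 0.0228. At 1 day in the dark these 5 loci stood at 17.1, 59.1, 135, 332 and 30.9, and in the other 3 libraries at 0.567 FPKM or less. Across loci, the 60-min library correlated most with the 1-day dark library (Pearson r = 0.855, Spearman rho = 0.845, loci not being independent replicates), against 0.829 and 0.812 with the 5-day dark library. On the lower side, transcription factor MYB44 (ZS06g0563500) was listed at 37.4 and 0, F-box protein AFR (ZS06g0577800) at 26.4 and 0, and RADIALIS-like 3 (ZS03g0150000) at 29.2 and 0.218. The KNOX shoot meristem list, with knotted-1-like 1 (ZS01g0217500) at 28.7 and 5.22, had a median of -0.87 (percentile 2.5), and of -0.60 (percentile 3.0, inside the random range) against the 3-day dark library. Root markers, which include the iron-nutrition enzyme nicotianamine synthase (ZS03g0203700) at 343 and 87.4 FPKM and aquaporin NIP2-1 (ZS02g0631400) at 29.5 and 16.1, had a median of -1.14 (percentile 1.0). Over all loci, 3512 were higher and 3039 lower than in the 5-day dark library, of which 1316 and 213 lay outside the range of the dark libraries. Scaled to the median ratio of loci the balance turned, to 3055 higher and 3248 lower, and with the 3-day dark library as control there were 5711 higher and 2114 lower.

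After 24 h of light, late embryogenesis abundant (LEA) and dehydrin loci, whose proteins protect cells that lose water, were higher than in the 5-day dark library at 10 of 17 and lower at 1 (median 1.79, percentile 100). Dehydrin Rab16D (ZS11g0389900) stood at 3.69 and 859 FPKM, and the group 3 LEA loci ZS05g0563700 and ZS01g0565700 at 5.86 and 195 and at 0.596 and 69.6. The abscisic acid list had a median inside the random range (-0.25). NADP-malic enzyme (ZS01g0608000) stood at 0.624 and 81.0, stem bromelain (ZS09g0427100), a cysteine protease, at 0.181 and 93.0, and lipid-transfer protein 2 (ZS05g0568900) was listed at 0 and 457. Glycine-rich cell wall protein 1 (ZS10g0351700) and dirigent protein 4 were listed at 0 in the 5-day dark library and at 47.9 and 92.3 after 24 h. In the 3-day dark library, however, dirigent protein 4 stood near its 24-h level, as given above.

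Lignin loci, peroxidases and expansins were higher at 24 h. Phenylpropanoid and lignin loci were at least 2-fold higher at 14 of 44 and lower at 4 (0.48, percentile 100), with cinnamyl alcohol dehydrogenase 4 (ZS11g0550900), the last step to lignin units, at 0.237 and 14.3 FPKM and laccase-6 (ZS01g0703600) at 0.491 and 3.97. Class III peroxidases were higher at 16 of 45 and lower at 1 (0.66, percentile 100). Peroxidase 2 (ZS03g0281700) stood at 3.21 and 60.4 and peroxidase 47 (ZS08g0019500) at 0.789 and 32.5. Expansins were higher at 10 of 26 and lower at 3 (0.83, percentile 100), with expansin-B3 (ZS10g0448300) at 19.3 and 97.2 and expansin-B6 (ZS10g0448200) at 16.7 and 72.6. CESA4 and CESA9 stood at 23.7 and 12.2 FPKM, against 23.7 and 13.0 in the dark. Against the 3-day dark library the medians of lignin loci and peroxidases were 0.35 and 0.31, inside the random range, and that of expansins 0.61 (percentile 97.9). Expansin-B6 stood at 72.6 FPKM in the 3-day dark library as well. The medians of xyloglucan endotransglucosylases (0.21) and primary wall cellulose synthases (0.54) lay inside the random range.

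Ribosomal proteins were higher at 47 of 97 and lower at 1 (0.99, percentile 100) and cell cycle loci at 18 of 38 (0.96, percentile 100). JAZ loci were higher at 4 of 11 (0.88, percentile 99.7), WRKY factors at 17 of 49 with 3 lower (0.26, percentile 99.1), and pathogenesis-related and chitinase loci at 11 of 27 with 5 lower (0.65, percentile 100). Auxin synthesis, conjugation and transport loci were higher at 6 of 19 and lower at 2 (0.50, percentile 99.3), with YUCCA10 (ZS01g0183100), an auxin synthesis enzyme, at 2.03 and 10.5. Aquaporins had 4 of 19 higher and 4 lower (0.51, percentile 98.2), with TIP2-1 at 12.7 and 170 FPKM. Their median lay inside the random range against the 3-day dark library (0.08, percentile 9.3). HY5 stood at 6.78 FPKM, COP1 at 13.5, PIF1 at 2.20 and phytochrome A at 43.9. GLK1 and GLK2 stood at 0.721 and 0.0668, phytochromes B and C at 11.6 and 2.67, cryptochromes 1 and 2 at 2.85 and 11.4, and the PIF4 loci at 2.25 and 1.01. Gibberellin 20-oxidase 1 stood at 22.7 and D14L at 67.1, near their 5-day dark levels of 21.1 and 82.4, and the gibberellin 2-oxidase ZS01g0620700 at 3.69. The gibberellin list median lay inside the random range (0.10). Its early-step loci were ent-kaurene synthase 1 (ZS04g0742800 and ZS04g0742850 merged), at least 2-fold lower at 15.3 and 5.28, and ent-kaurene oxidase 2 (ZS06g0484500) at 9.38 and 6.40. Below 3 FPKM in each of the dark 5-day and 24-h libraries lay the 2-oxidase loci ZS05g0063700 (1.71 and 2.19), ZS05g0578000 (2.06 and 2.46), ZS01g0112100 (0.963 and 0.586) and ZS04g0634900 (0 and 1.17), and the 20-oxidase locus ZS01g0733800 (0.829 and 0.0350).

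Photosystem and carbon fixation loci were lower at 24 h than in the 5-day dark library at 9 of 16 and higher at 2 (-1.59, percentile 0.0), chlorophyll biosynthesis at 5 of 8 (-1.77, percentile 0.0) and antenna loci at 3 of 7 (-0.72, percentile 5.1). Against the 3-day dark library these medians were 0.68, 0.83 and 1.56 (percentiles 98.8, 96.6 and 99.9). The pathway Carbon fixation in photosynthetic organisms lay inside the random range against the 5-day dark library (percentile 22.1), with its chloroplast-named loci at -1.51 (percentile 0.0). Shoot meristem markers were lower at 3 of 4 (-1.21, percentile 0.5), and root markers higher at 3 of 4 (1.20, percentile 99.2), with nitrate transporter 2.3 (ZS01g0564800) at 0.369 and 10.9 FPKM. The light-signalling median was -0.64 (percentile 1.7), and 0.28 against the 3-day dark library. Heat shock proteins had a median of -0.35 (percentile 1.1), and of 0.04 against the 3-day dark library, also low among matched lists (percentile 2.0). The 24-h seedlings were also 1 day older than the 5-day dark seedlings, and no dark library of that age was analysed here. Over all loci, 2750 were higher and 3436 lower, of which 1102 and 271 lay outside the range of the dark libraries. With the 3-day dark library as control the balance turned, to 3526 higher and 1547 lower.

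**Figure D3:**
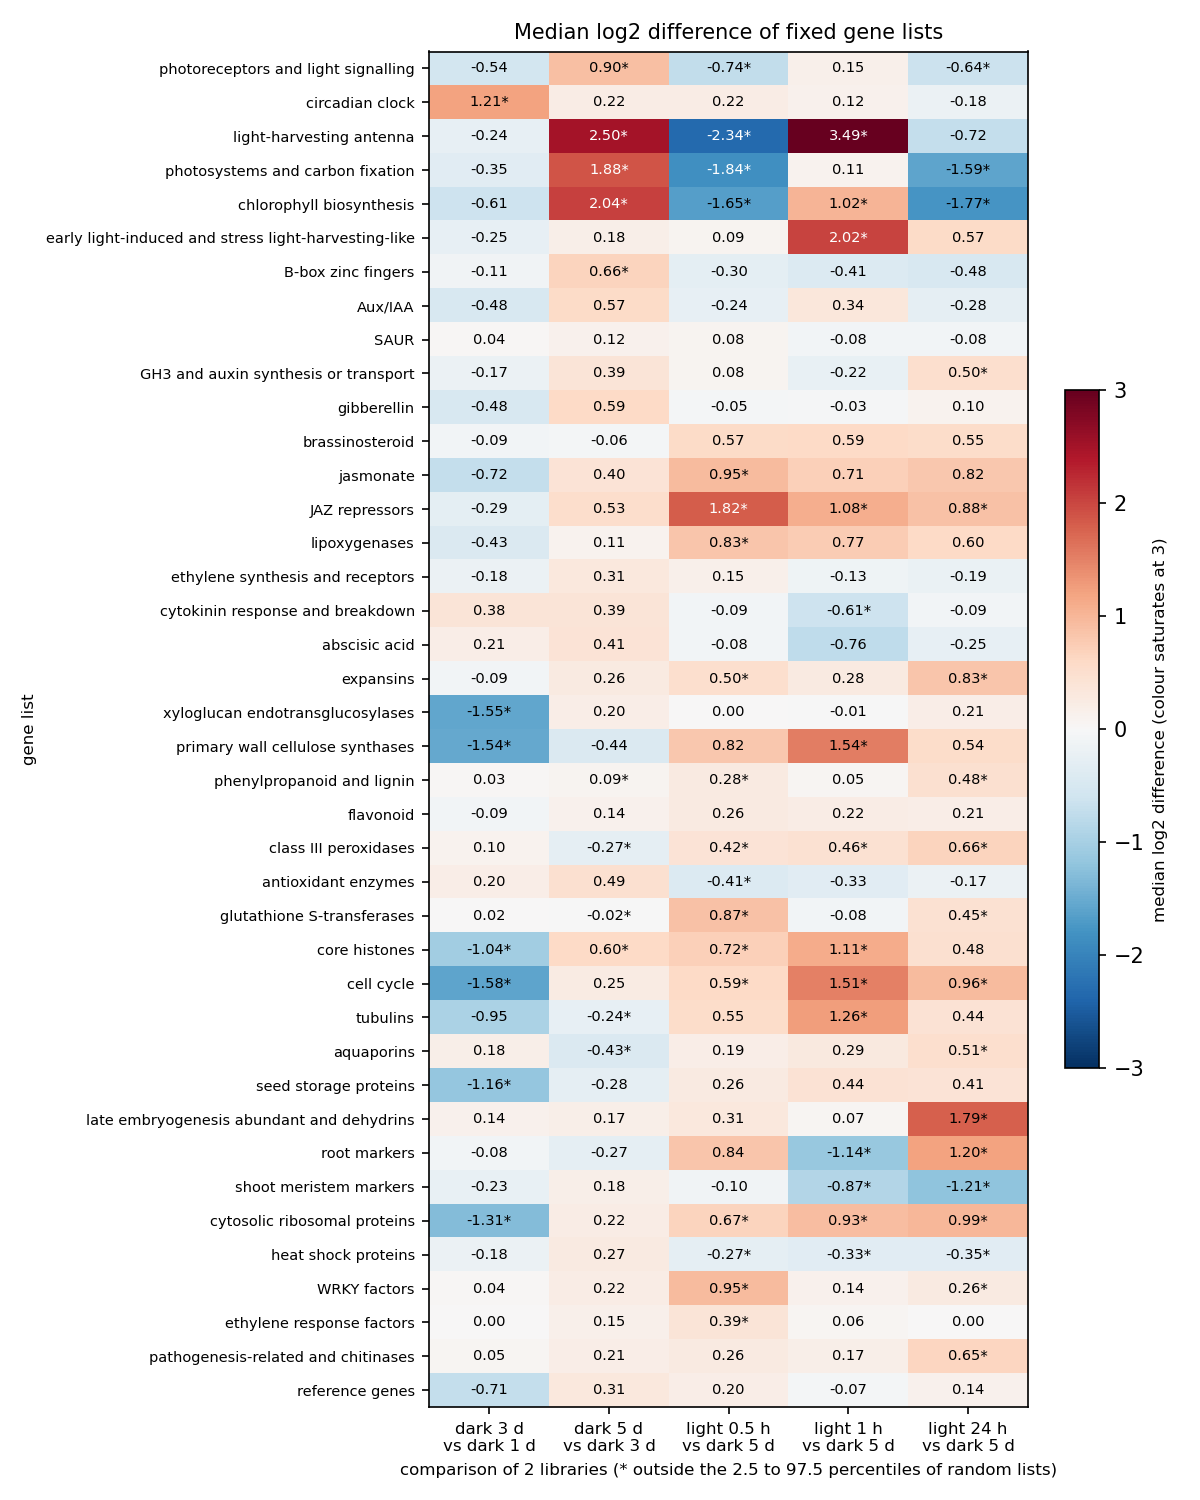
Median log2 difference of 40 fixed gene lists (rows) in the 5 main comparisons (columns), with colour from blue (lower) to red (higher); a star marks medians outside the random range. Antenna loci run from 2.5 (5 against 3 days of darkness) to -2.34 (30 min of light) and 3.49 (60 min), and LEA and dehydrin loci reach 1.79 at 24 h.

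Between the light libraries, 3627 loci were higher and 2806 lower after 60 min than after 30 min. Antenna (6.32), photosystem (3.29) and chlorophyll (2.68) medians were at the 100 percentile. The pathway Carbon fixation in photosynthetic organisms went the other way (-0.39, percentile 0.0), with 23 of 131 loci higher and 27 lower; its 21 chloroplast-named loci lay at 1.21 (percentile 100) and the other 110 at -0.48 (percentile 0.0). JAZ (-0.65, percentile 1.3), WRKY (-0.73, percentile 0.0), glutathione S-transferase (-0.88, percentile 0.0) and root marker (-1.97, percentile 0.0) medians were low. From 60 min to 24 h, 2533 loci were higher and 3598 lower. The antenna, photosystem and chlorophyll medians were -4.85, -3.06 and -3.04 (each at percentile 0.0), and that carbon fixation pathway lay at 0.19 (percentile 100), with its chloroplast-named loci at -1.22 (percentile 0.0) and the others at 0.28 (percentile 100). Cell cycle loci lay at -0.50 (percentile 0.1), and LEA and dehydrin loci (1.38), lignin loci (0.59) and root markers (2.56) lay at the 100 percentile. The 30-min and 24-h libraries were the closest pair across loci (Pearson r = 0.907, Spearman rho = 0.890). Between them, with the 60-min library left out, 1481 loci were higher at 24 h and 1816 lower.

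The authors' deposited table marks 6933 loci as significant, each with an authors' p under 0.05, and 2530 loci have an authors' q under 0.05. The table gives 1 p and 1 q per locus over the 6 libraries and does not state the test or the libraries compared.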

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

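Of the 9 tests of explanations below, 7 were chosen after the result was seen; those on plastid ribosomal proteins and on cuticle loci were written before their values were computed.

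Of the gene lists fixed before the data were examined, those were singled out whose medians against the 5-day dark library lay outside the random range on opposite sides at different light times. With 1 library per time, the difference was not tested. The antenna list (7 loci) lay at 3.49 after 60 min and at -2.34 after 30 min of light, 5.84 apart. Chlorophyll biosynthesis (8 loci) lay at 1.02 after 60 min, against -1.65 after 30 min (2.67 apart) and -1.77 after 24 h (2.79 apart). Root markers (4 loci) lay at 1.20 after 24 h and at -1.14 after 60 min, 2.34 apart. The plastid ribosomal protein list (19 loci), added later, also lay on opposite sides, at 0.82 after 60 min, -2.83 after 30 min and -2.35 after 24 h.

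Photosynthesis loci, pooled, were high in the 5-day dark and 60-min libraries, low in the 3-day dark and 30-min libraries and in between after 24 h, with antenna, photosystem and chlorophyll medians at -0.72, -1.59 and -1.77 against the 5-day and at 1.56, 0.68 and 0.83 against the 3-day dark library. A light response as the whole cause is argued against by the pooled median of 31 loci, 2.14 higher at 5 than at 3 days of darkness. Depth or scaling, which moves loci of matched expression alike, is argued against by the pooled median at the 4 steps between these libraries, at least 1.85 from the median over all loci in the direction of the pattern and outside the range of matched random lists each time. The pooled loci are those in which the pattern was seen, so this restates it. Plastid ribosomal proteins, not used to see it, also lay outside the random range at these steps (2.78, -2.83, 3.49 and -3.08). Green shoot tissue in the 2 high samples stays open as a hypothesis: plastid ribosomal proteins (19 loci) were 2.78 higher at 5 than at 3 days of darkness and 3.49 higher after 60 than after 30 min (each at percentile 100), though plastid growth within the mesocotyl could give the same. More of the same tissue as the whole cause of the higher antenna loci at 60 min than at 5 days of darkness is argued against by their median. It exceeded the photosystem and carbon fixation median by 3.38, but that list was mixed, with 6 of 16 loci higher and 2 lower. Plastid ribosomal proteins were also higher there (0.82, percentile 100), so some more green tissue is not excluded. A light response of the antenna loci also stays open.

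The 60-min library was closer to the 1-day dark library than to any other. An exchange of the 2 libraries is argued against by HY5, COP1 and the early light-inducible loci, at least 1.49 higher on the log2 scale in the library labelled 60 min. RNA of the 1-day sample mixed in as the whole cause is argued against by the loci that were high at 1 day and under 2 FPKM in the other 4 libraries. Their ratios of 60 min to 1 day spread 147-fold between the 10th and 90th percentile, and 2 of the 5 were above 1, but 5 loci are few. Surface tissue of young shoots in both samples may account for part and stays a hypothesis, as 21 cuticle and epidermis loci were 1.26 higher after 60 than after 30 min and 0.80 higher at 1 than at 3 days of darkness, each at percentile 100, whereas the pathway Cutin, suberine and wax biosynthesis (72 loci, members both higher and lower) lay at -0.11 and inside the random range after 60 against 30 min. Shoot meristem markers were not higher after 60 than after 30 min (-0.89, percentile 3.0), with 0 of 4 loci at least 2-fold higher and 1 lower.

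The JAZ loci were highest after 30 min of light. An unusually low 5-day dark library is argued against by the median of 11 loci, 2.60 above the 3-day and 1.71 above the 1-day dark library. Handling or wounding at sampling could also raise jasmonate loci, and it cannot be told apart from light here: the median of 1.82 above the 5-day library has no dark library handled at the same time beside it. A response to light stays open and untested.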

How the results depend on the processing

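The alternatives that leave out a library, that leave out loci listed at 0, that scale to the mean of the 6 library sums and that average the 3-day and 5-day dark libraries were chosen after seeing the data; the others were fixed before the data were examined. No paired analysis was possible because each group held 1 library. With no filter the counts cannot change, since a locus under 1 FPKM in every library cannot reach 2-fold at this pseudocount. Of the other 122 alternative counts, 70 lay within 1.5 times the reported count, 14 were above and 38 below that range. All 14 counts of the 7 comparisons lay within it with median-ratio, mean-sum and TPM scaling, the last of which also lowers the weight of the pseudocount. The balance of higher against lower turned all the same, for 3 against 1 day of darkness under all 3 and for 60 min of light under median-ratio scaling. Depth is not known from FPKM values, so how much of any difference at low expression is counting error stays open.

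With a pseudocount of 0.1, which enlarges differences of low loci, 10 counts were above the range. They were 5239 higher and 5260 lower for 3 against 1 day of darkness, and 5896 and 1952 for 5 against 3 days. For 30 min against darkness they were 3791 and 4198, for 60 min 4626 lower, for 24 h 4260 higher, for 60 against 30 min 4605 lower and for 24 h against 60 min 3941 higher. With a pseudocount of 5, which shrinks them, all 14 were below: 1121 and 1522, 999 and 292, 711 and 854, 1379 and 966, 895 and 1119, 1445 and 912, and 880 and 1410, higher and lower in the same order. A filter of at least 5 FPKM, which leaves fewer loci, gave 2135 and 609 for 5 against 3 days, 1434 and 1578 for 30 min, 1807 lower for 60 min, 1809 and 2098 for 24 h, 2405 and 1862 for 60 against 30 min and 1625 higher for 24 h against 60 min. Without loci listed at 0 in either library, the lower count for 5 against 3 days was 708.

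With the 3-day dark library as control, 3 of 6 counts lay outside the range: 1166 lower at 30 min, 5711 higher at 60 min and 1547 lower at 24 h; the cause was not tested. The higher counts at 30 min and 24 h were 3058 and 3526, so the balance turned at both. The mean of the 3-day and 5-day libraries gave 1230, 1860 and 1663 lower. Outside the range of all 3 dark libraries, which is stricter by construction, there were 1088 and 182, 1316 and 213, and 1102 and 271. Without the 3-day dark library, 5 against 1 day gave 5575 higher and 2707 lower, and without the 60-min library 24 h against 30 min gave 1481 and 1816; the cause was not tested.

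Of 280 list medians, 99 lay outside the random range; under other pseudocounts, no filter and both scalings the number lay between 97 and 104, and with the 5 FPKM filter it was 109 of 266. Of the 99, 92 and 95 kept their side with pseudocounts of 0.1 and 5, 88 with no filter, 91 with the 5 FPKM filter, 98 with median-ratio and 96 with TPM scaling. With the 3-day dark library as control, of the 50 outside at light times 29 kept their side, 19 lay inside the random range and 2 lay on the other side, peroxidases at 30 min (high to low) and photosystem and carbon fixation at 24 h (low to high). In sign 10 turned, 2 of them (heat shock proteins) still low among matched lists. These 10 were light signalling (0.08 at 30 min, 0.28 at 24 h), antenna (0.04 at 30 min), photosystem and carbon fixation (0.13 and 0.68), chlorophyll biosynthesis (0.22 and 0.83), antioxidant enzymes (0.10 at 30 min) and heat shock proteins (0.12 and 0.04). The median over all loci was 0.27 higher at 5 than at 3 days of darkness, so a sign against the 3-day library is to be read with that offset. The abscisic acid median for 60 against 30 min was 0.04 with no filter, and the lignin median for 5 against 3 days -0.04 with median-ratio scaling; the cause was not tested. Of 1103 named values at 2-fold or more, 54 were under 2-fold with median-ratio scaling. In simulated lists with no shift, 5 of 100 reached the upper limit of the random range. Their loci varied independently, so this does not cover lists whose loci move together.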

Other observations

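The pathways in this part were chosen after the values had been seen, among 115 pathways of the authors' deposited table with 10 to 300 loci. Each was set against 2000 random lists of matched expression in 7 comparisons. Many lay outside the random range, so such a percentile alone does not set a pathway apart. High and low pathways numbered 16 and 17 at 3 against 1 day of darkness and 4 and 25 at 5 against 3 days. Against 5-day darkness they numbered 21 and 4 after 30 min, 16 and 7 after 60 min and 24 and 4 after 24 h. For 60 against 30 min they numbered 12 and 28, and for 24 h against 60 min 19 and 9. Loci of the Proteasome pathway (87 loci), which degrades tagged proteins, had a median of -0.63 at 3 against 1 day of darkness (percentile 0.0) and of 0.43, 0.35 and 0.52 after 30 min, 60 min and 24 h of light against 5-day darkness (percentiles 100, 99.6 and 100). Against the 3-day dark library these were 0.49, 0.36 and 0.70, with those at 30 and 60 min inside the random range (percentiles 97.3 and 50.0). The Citrate cycle (TCA cycle), the core of respiration, had 63 loci with a median of -0.55 at 3 against 1 day (percentile 1.1), 0.45 after 30 min (percentile 100), 0.22 after 60 min (percentile 83.4) and 0.36 after 24 h (percentile 98.5), the last inside the random range against the 3-day dark library (0.53, percentile 96.8). DNA replication (124 loci) lay at -0.49 at 3 against 1 day, with 30 loci at least 2-fold lower and 2 higher (percentile 0.0), and at 0.30 after 60 min, with 35 higher and 8 lower (percentile 99.8). Nitrogen metabolism (41 loci) lay at 0.49 after 24 h, with 9 higher and 4 lower (percentile 100).

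Fatty acid elongation, which makes the long chains of waxes, had 51 loci. After 60 min of light 21 of them were at least 2-fold higher than in 5-day darkness and 4 lower (median 0.54, percentile 100), and after 24 h 2 were higher and 21 lower than after 60 min (-0.66, percentile 0.0). The pathway Cutin, suberine and wax biosynthesis (72 loci) lay at -0.11 after 60 against 30 min (percentile 6.5), with 14 higher and 13 lower. Brassinosteroid biosynthesis, for a hormone of cell elongation, had 31 loci with a median of 0.54 at 3 against 1 day of darkness (percentile 99.8). After 60 min it lay at -0.67 against 30 min, with 11 loci at least 2-fold lower and 3 higher (percentile 0.0). Against 5-day darkness it lay at 0.01, -0.29 and -0.12 after 30 min, 60 min and 24 h of light (percentiles 57.1, 2.5 and 32.9). From 60 min to 24 h it lay at 0.23 (percentile 98.7).

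The locus with the highest share of the 3-day dark library, ZS07g0251700, has no product name in the deposited table. It stood at 50093 FPKM there and at 10022 after 24 h of light. The locus ZS07g0251600, next to it by name, was listed at 5418 FPKM at 1 day of darkness, at 7428 after 30 min of light and at 0 in the other 4 libraries. Such 0 values can be failed estimates, so these neighbours may not have separate patterns. The chloroplast NADH-plastoquinone oxidoreductase locus ZS04g0334000 stood at 129 FPKM at 5 days of darkness and 43.4 after 60 min, against 11.7 at 3 days, 1.19 after 30 min and 3.47 after 24 h.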
